A study of Mus musculus with 20 samples.

How the data were processed

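RNA was measured on 20 Affymetrix Mouse Gene 2.0 ST arrays, a platform that reads whole transcripts with many probes per gene. Per the labels, 15 arrays held mouse acute myeloid leukaemia samples in 5 groups of 3 and 5 held normal controls (NC). CD45.1+ donor cells had been sorted by flow cytometry from the marrow of transplant recipients at the end stage, and total RNA had been isolated with a miRNeasy kit. The groups were taken from the sample titles. MA9 stands for the MLL-AF9 fusion, in which the histone methyltransferase gene Kmt2a is joined to Mllt3. The labels do not say whether arrays of a group came from separate animals, so that the p-values measure the spread between samples. The sex of donors and recipients, the species of the transduced constructs and any array batch are not given in the sources used here.

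The deposited values are log2 expression values, which the authors made with RMA in Partek 6.0. The genome build, the probe set library and the parameters are not given in the sources used here. The values ran from 2.82 to 14.0 and the array medians from 7.20 to 7.31. Arrays have no count depth, so the number of arrays limits the precision. Raw intensities were not used here.

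Of 41345 probe sets, 23521 carried a single gene symbol, 1814 carried several and 16010 had none listed. The single-symbol probe sets gave 22180 genes. For the 1082 genes with several probe sets, the one with the highest mean over all arrays was used. Entrez numbers of 23328 probe sets matched the RefSeq gene table, which changed 0 symbols. Of the called genes of MA9 against NC, 61 had several probe sets, and for 11 of these at least 1 probe set had the opposite sign.

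All 22180 genes were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over the 20 arrays and moderated variances (14 residual degrees of freedom, prior 3.92). A total of 14 comparisons were made. P-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called changed with an adjusted p under 0.05 and a log2 fold change of at least 1 in size. Values after ± are standard errors of the fit unless called SD.

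Before the data were examined, 29 gene lists of 500 genes were fixed, of which 454 genes were measured. Each list was tested against all other genes in each comparison with camera at a preset correlation of 0.01, which gave 406 tests adjusted together. The same tests were run with a correlation estimated per list, and with fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes. The words rose and fell are used for genes called changed and for lists past the camera test.

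The rule for the genes named was also set before the data were examined. It takes the 6 genes with the largest positive and the 6 with the largest negative log2 fold change for each comparison with NC and for PBX3+MEIS1 against MA9, and 3 and 3 for each other comparison. They had to be called changed, with no overlap between the arrays of both groups. Predicted or unnamed genes, olfactory and vomeronasal receptors and segments of immunoglobulin and T cell receptor genes were left out. It adds the transduced genes, up to 4 members by smallest adjusted p of a list that passed and is described, the members of the HOXA cluster and MLL-fusion target lists, and the 8 risen and 8 fallen genes with the largest mean change among those changed in all 5 comparisons with NC.

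Fold changes against NC were correlated across genes between MA9 and each other leukaemia, which makes 4 correlations. Both sides of each correlation share the NC arrays. The correlation was therefore also computed on simulated data without group effects and with the NC arrays split between both sides. Genes are not independent replicates, so no p-value is given for these correlations.

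The fit was tested on simulated data with 200 changed genes in each of 10 simulations. At a log2 change of 1.5, it recovered 98.7% of the genes for MA9 against NC and 98.6% for PBX3+MEIS1 against MA9, with 0.5 and 0.8 false calls on average. Camera called a shifted list in 10 of 10 simulations, with 0.2 other lists called on average. These simulations drew the genes independently of each other, with the same spread of a gene in every group. Their rates therefore do not cover lists of correlated genes or groups with an array that stands apart.

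The alternatives tried were a filter on low values (12208 genes kept), the mean of all probe sets of a gene, centring each array, a further quantile normalization, variance moderation with a trend and robust to unusual genes, array weights, no fold minimum, only both compared groups in the fit, the replicate number as a block, only 3 of the NC arrays, Spearman correlation, genes changed in either leukaemia, and leaving out each array in turn. After the data were seen, fits without the 922 genes on X and Y, list tests without NC array 1 or PBX3+MEIS1 array 3, and a Spearman correlation and shared calls without the latter array were added.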

Results

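The arrays compared donor-derived marrow cells of mice with 5 kinds of acute myeloid leukaemia and of normal controls. The leukaemias carried MLL-AF9 (MA9), HOXA9, HOXA9+MEIS1, HOXA9+PBX3 or PBX3+MEIS1, with 3 arrays each, and NC had 5 arrays. HOXA9 is a homeobox transcription factor, and MEIS1 and PBX3 are homeobox proteins of the TALE class that bind DNA together with HOX proteins. Pairs of arrays within NC correlated at 0.990 to 0.997 across genes. The corresponding ranges were 0.983 to 0.993 for MA9, 0.993 to 0.995 for HOXA9, 0.987 to 0.991 for HOXA9+MEIS1, 0.995 to 0.996 for HOXA9+PBX3 and 0.968 to 0.991 for PBX3+MEIS1. The first principal component held 41.1% of the variance, the second 14.5% and the third 11.8%. PBX3+MEIS1 array 3 stood at -63.4 on the third component. Its median signal of olfactory and vomeronasal receptor genes, which marrow cells are not known for, was 5.73, against 4.76 to 5.19 on the other 19 arrays.

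**Figure D1:**
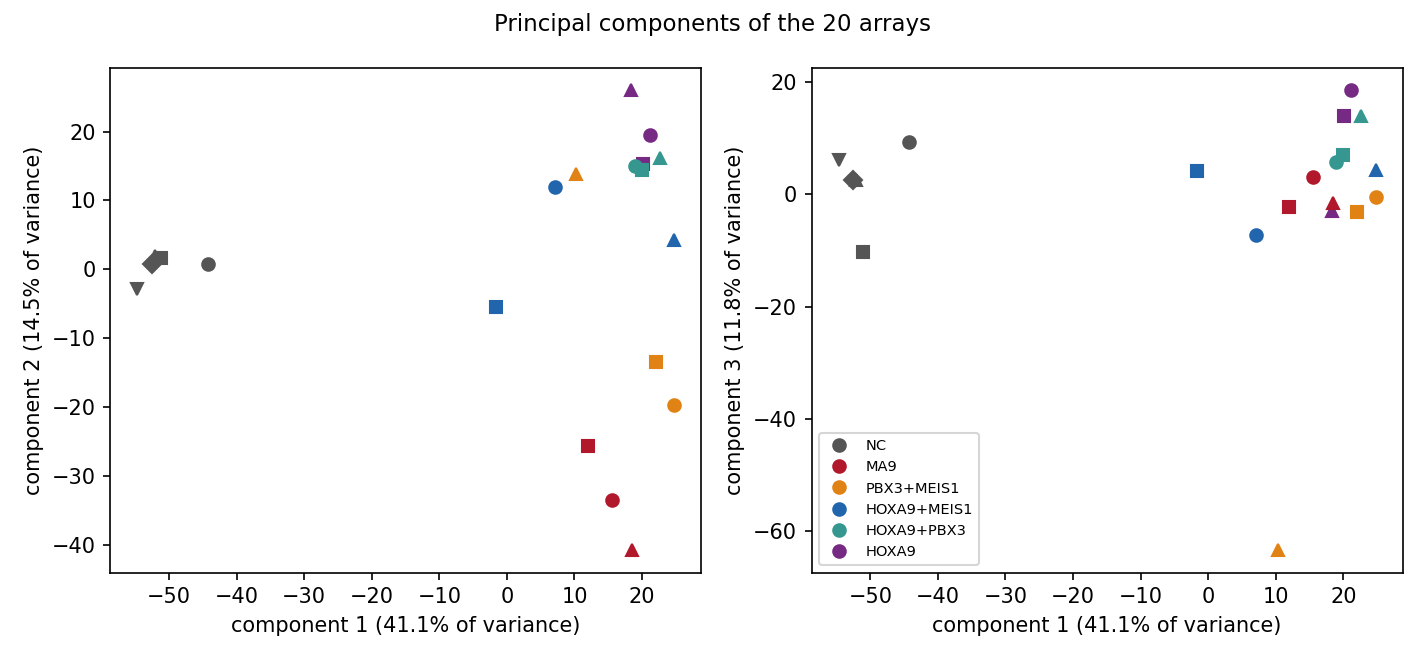
Scores of the 20 arrays on principal components 1 and 2 (left) and 1 and 3 (right), each point an array, coloured by group and shaped by replicate number. The NC arrays lie apart from the leukaemias on component 1, and PBX3+MEIS1 array 3 lies at -63.4 on component 3.

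The levels of Hoxa9, Meis1 and Pbx3, the mouse genes that correspond to the transduced ones, were compared between groups first. Hoxa9 (probe set 17466863) had a mean log2 value of 7.09 ± 0.23 (SD, n = 5) in NC. It was 10.81 ± 0.15 (SD, n = 3) in MA9 and 10.49 ± 0.67 (SD, n = 3) in PBX3+MEIS1, neither of which carried a HOXA9 construct. It was 8.23 ± 0.29 in HOXA9, 8.03 ± 0.22 in HOXA9+MEIS1 and 8.11 ± 0.12 in HOXA9+PBX3 (SD, n = 3 each). Meis1 had a mean of 8.38 ± 0.44 in NC (SD, n = 5), 11.81 ± 0.09 in MA9, 10.39 ± 0.21 in HOXA9, 10.25 ± 0.07 in HOXA9+PBX3, 9.77 ± 0.46 in HOXA9+MEIS1 and 10.30 ± 1.5 in PBX3+MEIS1 (SD, n = 3 each). Pbx3 had a mean of 8.09 ± 0.02 in NC (SD, n = 5), 10.56 ± 0.89 in MA9, 10.78 ± 0.23 in PBX3+MEIS1, 9.78 ± 0.45 in HOXA9+PBX3, 9.14 ± 0.02 in HOXA9 and 8.26 ± 0.12 in HOXA9+MEIS1 (SD, n = 3 each). Whether the probes read the constructs is not given in the sources used here, so that the levels of Hoxa9, Meis1 and Pbx3 are no measure of the transduced proteins.

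**Figure D2:**
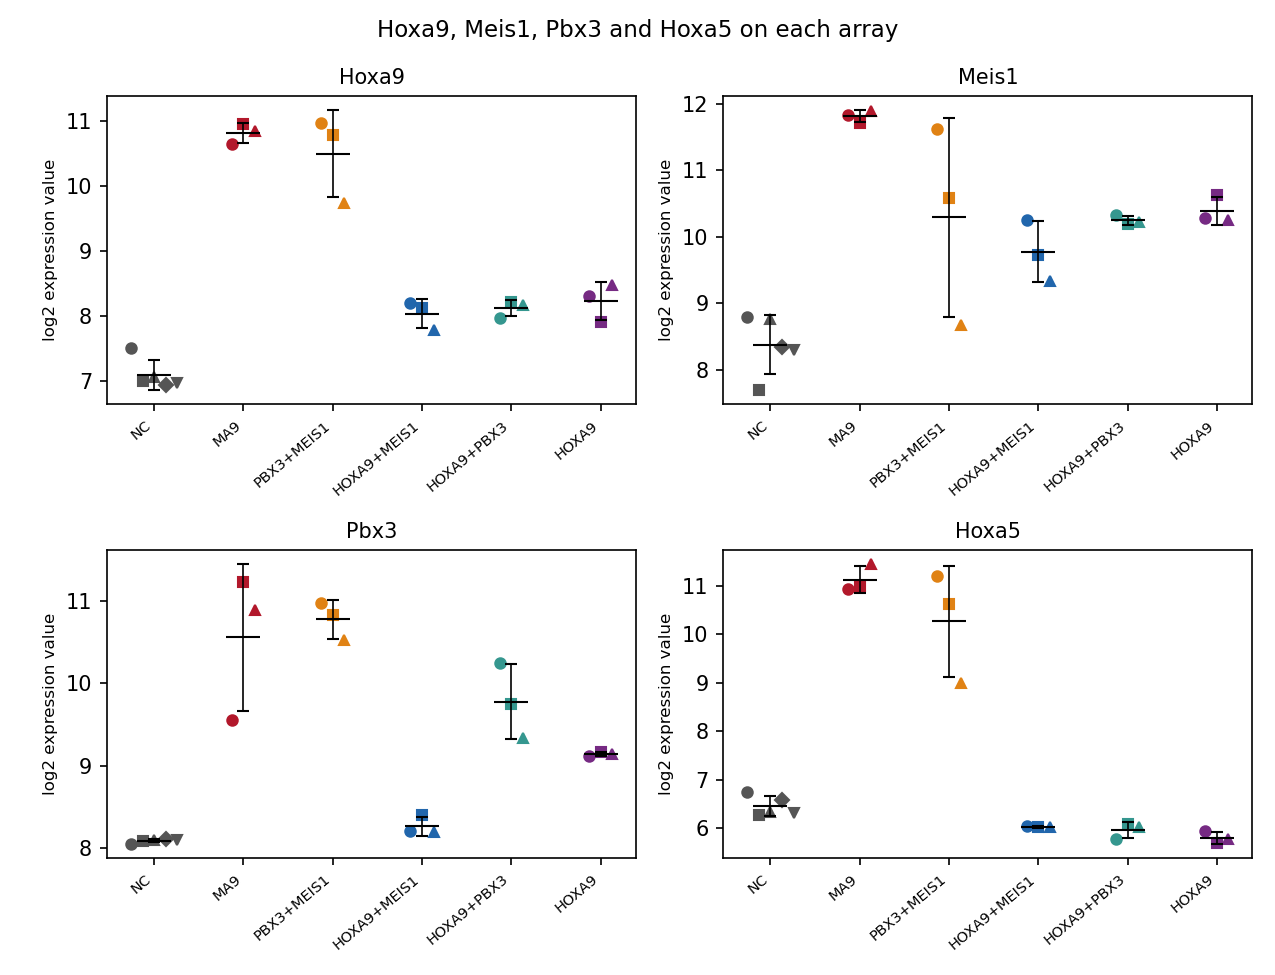
Log2 expression values of Hoxa9, Meis1, Pbx3 and Hoxa5 on each array by group, with points for arrays (shape gives the replicate number), a horizontal line for the group mean and bars for 1 SD. Hoxa9 had means of 10.81 in MA9 and 10.49 in PBX3+MEIS1 and of 8.03 to 8.23 in the 3 groups that carried HOXA9.

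MA9 was compared with NC to describe the leukaemia of the MLL fusion. In MA9, 379 genes were higher and 769 lower, 1148 in all. The largest rise was that of Tcf24, a basic helix-loop-helix transcription factor gene (log2 fold change 4.79 ± 0.18, adjusted p = 3.48e-12). Hoxa5 (4.68 ± 0.31), Hoxa6 (4.07 ± 0.26) and Hoxa9 (3.72 ± 0.21, adjusted p = 1.07e-09) rose beside Igf2bp3, which encodes an RNA-binding protein (4.12 ± 0.19), and Hpgd, which encodes a prostaglandin-degrading enzyme (3.78 ± 0.22). Meis1 rose by 3.44 ± 0.42 and Pbx3 by 2.47 ± 0.26. The genes that fell most were Ankrd22 (-4.82 ± 0.50), Ptgs2, the inducible cyclooxygenase gene (-4.49 ± 0.53), Car2, a carbonic anhydrase gene of red cells (-4.34 ± 0.34), Il1b, an inflammatory cytokine gene (-4.26 ± 0.40), Ms4a1, a B cell surface marker gene (-4.25 ± 0.19), and Il1f9, another cytokine gene (-4.12 ± 0.41). Mllt3 fell (-1.08 ± 0.10), and Kmt2a was under the fold minimum (-0.38 ± 0.10). Both had similar levels in the leukaemias without the fusion. The mean of Mllt3 was 7.59 to 7.87 there, 7.65 in MA9 and 8.74 in NC. That of Kmt2a was 10.16 to 10.47 there, 10.43 in MA9 and 10.82 in NC.

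The HOXA cluster list rose in MA9, with 8 of 9 measured members higher over all genes and 8 adjusted over the list alone (median log2 fold change 2.87, adjusted p = 3.07e-11, but adjusted p = 0.0941 with an estimated correlation). Hoxa7 rose by 3.01 ± 0.25. Of 22 measured MLL-fusion target genes, 11 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 5.92e-08, and adjusted p = 0.106 with an estimated correlation). They included Six4, a homeobox gene (2.28 ± 0.13). The list shares Hoxa9, Hoxa6 and Hoxa5 with the HOXA cluster list. In PBX3+MEIS1 against NC, the HOXA cluster rose with 8 of 9 members over all genes and 8 adjusted over the list alone (median 2.16, adjusted p = 9.6e-09, and adjusted p = 0.153 with an estimated correlation). The MLL-fusion targets rose there with 11 higher and 1 lower, and with 11 and 1 adjusted over the list alone (adjusted p = 2.42e-05, and adjusted p = 0.236 with an estimated correlation). Eya1, a transcriptional coactivator gene of this list, rose by 2.89 ± 0.20.

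PBX3+MEIS1 was compared with NC to describe the leukaemia made without a HOXA9 construct. There, 272 genes were higher and 775 lower, 1047 in all. Without PBX3+MEIS1 array 3, 442 were higher and 800 lower. The genes that rose most were Igf2bp3 (4.30 ± 0.19), Hpgd (3.96 ± 0.22), Hoxa5 (3.82 ± 0.31, adjusted p = 6.46e-08), the collagen gene Col19a1 (3.49 ± 0.25), Hoxa9 (3.40 ± 0.21) and Fnbp1l (3.31 ± 0.37). Those that fell most were Ankrd22 (-5.17 ± 0.50), Car2 (-4.87 ± 0.34), Il1f9 (-4.86 ± 0.41), Dhrs9, a dehydrogenase gene (-4.64 ± 0.39), Car1, another carbonic anhydrase gene (-4.57 ± 0.39), and Hdc, which encodes the enzyme that makes histamine (-4.51 ± 0.34). Pbx3 rose by 2.69 ± 0.26. Meis1 rose by 1.92 ± 0.42 (1.25 without PBX3+MEIS1 array 1). Its log2 values were 11.63, 10.59 and 8.67 on PBX3+MEIS1 arrays 1, 2 and 3 and 7.70 to 8.79 in NC, so that only array 3 overlapped NC.

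The leukaemias with HOXA9 were compared with NC in the same way. HOXA9 alone had 277 genes higher and 766 lower. Gpnmb, which encodes a membrane glycoprotein, rose by 4.95 ± 0.34, Igf2bp3 by 4.28 ± 0.19, Hpgd by 4.16 ± 0.22, the coagulation factor gene F7 by 3.68 ± 0.35 and the scavenger receptor gene Colec12 by 3.60 ± 0.42. The Y-linked gene Eif2s3y was higher by 3.71 ± 1.18 (adjusted p = 0.0287), a call lost on leaving out any single HOXA9 array, without NC array 3, 4 or 5, or with the replicate number as a block. Ly6g, a surface marker gene of neutrophils, fell most (-5.85 ± 0.67), followed by Il1b (-5.06 ± 0.40), Ankrd22 (-4.69 ± 0.50), Car2 (-4.69 ± 0.34), Car1 (-4.59 ± 0.39) and Mctp2 (-4.51 ± 0.40). Hoxa9 rose by 1.14 ± 0.21, Meis1 by 2.01 ± 0.42 and Pbx3 by 1.06 ± 0.26.

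HOXA9+MEIS1 had 195 genes higher and 633 lower than NC. Igf2bp3 (4.41 ± 0.19) and Hpgd (4.04 ± 0.22) rose most, followed by Slc18a1, a vesicular monoamine transporter gene (3.83 ± 0.29), Gpnmb (3.59 ± 0.34), Stfa2, which encodes an inhibitor of cysteine proteases (3.48 ± 0.54), and the Y-linked gene Uty (3.47 ± 0.93). The call of Uty was lost without HOXA9+MEIS1 array 3 and with the replicate number as a block. Car2 (-5.02 ± 0.34), Car1 (-4.55 ± 0.39), the fatty acid desaturase gene Scd1 (-4.30 ± 0.27), Ms4a1 (-4.21 ± 0.19), the complement regulator gene Cd55 (-4.05 ± 0.23) and Il1f9 (-3.90 ± 0.41) fell most. Hoxa9 was under the fold minimum (0.94 ± 0.21), though it passed in 6 alternatives, among them the fit without NC array 1 (1.04). Pbx3 was not called (0.17 ± 0.26), and Meis1 rose by 1.40 ± 0.42 (adjusted p = 0.0256), a call lost without NC array 2, without HOXA9+MEIS1 array 1 or 2, with only 3 of the NC arrays and with the replicate number as a block.

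HOXA9+PBX3 had 256 genes higher and 758 lower than NC. Gpnmb (4.80 ± 0.34), Igf2bp3 (4.14 ± 0.19), Hpgd (4.13 ± 0.22), Tmem178 (3.57 ± 0.44), F7 (3.19 ± 0.35) and Rasgrf2, which encodes an exchange factor for small GTPases (2.95 ± 0.16), rose most. Car2 (-5.14 ± 0.34), Car1 (-5.10 ± 0.39), Il1b (-5.08 ± 0.40), Xist, the transcript of the inactive X chromosome (-4.82 ± 0.72), Mctp2 (-4.67 ± 0.40) and Ptgs2 (-4.65 ± 0.53) fell most. Pbx3 rose by 1.69 ± 0.26 and Meis1 by 1.87 ± 0.42. Hoxa9 rose by 1.02 ± 0.21, which came under the fold minimum in 6 alternatives.

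Changes common to the leukaemias were counted over the 5 comparisons with NC, all of which share the NC arrays. A total of 49 genes were higher and 384 lower in all 5, where independent calls would give 5.89e-06 and 0.000905. Simulated data without group effects gave 0, which cannot gauge the overlap, since calls are rare there in every comparison. Part of this overlap may come from the NC arrays, which are too few to be split between 5 comparisons. Without a fold minimum, more genes were higher than lower in MA9 (3333 and 2431), HOXA9 (2748 and 2259) and HOXA9+PBX3 (2996 and 2202). The mean log2 fold changes of the highest were 4.25 for Igf2bp3, 4.01 for Hpgd, 3.90 for Gpnmb, 2.81 for Colec12, 2.58 for Rasgrf2, 2.53 for Klhl41, 2.50 for F7 and 2.45 for Pyroxd2. Those of the lowest were -4.81 for Car2, -4.54 for Car1, -4.42 for Il1b, -4.30 for Il1f9, -4.28 for Ms4a1, -4.27 for Ankrd22, -4.23 for Ptgs2 and -4.15 for Cd55. In MA9, the calls of Colec12 (1.65 ± 0.42) and F7 (1.45 ± 0.35) were lost without MA9 array 1.

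Several lists of mature blood cell markers, though not that of monocytes and macrophages throughout, were lower in the leukaemias than in NC, which were sorted by the same donor marker. B lineage genes fell in all 5 leukaemias, with 14 of 18 measured members lower in MA9, HOXA9, HOXA9+MEIS1 and HOXA9+PBX3 and 13 in PBX3+MEIS1, and the same counts adjusted over the list alone. The medians ran from -2.51 in PBX3+MEIS1 to -2.63 in HOXA9, and the test held in all 5 with an estimated correlation (highest adjusted p = 0.0123). In MA9, Cd79a, a part of the B cell receptor, fell by 3.70 and Ebf1, a B lineage transcription factor gene, fell by 3.68. Erythroid genes fell with 12 of 16 members in each leukaemia, also 12 adjusted over the list alone, with 1 member higher in MA9 (medians -1.43 to -1.53), and held with an estimated correlation (highest adjusted p = 0.0439). Ermap, a red cell membrane gene, fell by 3.20 in MA9.

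Late neutrophil genes, 27 measured, fell with 17 members in MA9, 21 in HOXA9, 10 in HOXA9+MEIS1, 17 in HOXA9+PBX3 and 21 in PBX3+MEIS1. The counts adjusted over the list alone were 18, 21, 11, 19 and 21. In the same order, the medians were -1.52, -1.94, -0.81, -1.40 and -1.60, and all 5 calls were lost with an estimated correlation (adjusted p = 0.163, 0.0625, 0.279, 0.0939 and 0.0939). In PBX3+MEIS1, the list's median log2 value was 11.93 on array 3, against 10.59 and 10.46 on arrays 1 and 2. It was 12.81 to 12.91 in NC, so that the fall was smaller on array 3. Cxcr2, a chemokine receptor gene of neutrophils, fell in HOXA9 (-3.99) and in HOXA9+MEIS1 (-1.95). T and NK cell genes, 19 measured, fell with 9 to 11 members, the same adjusted over the list alone, and lost the call in each leukaemia (adjusted p = 0.0586 to 0.0941 with an estimated correlation). In MA9, Cd3g, a part of the T cell receptor complex, fell by 2.83. MHC class II genes, 10 measured, fell with 7 members in 4 leukaemias and 6 in HOXA9, the same adjusted over the list alone. With an estimated correlation, the call was kept in MA9 (adjusted p = 0.0458) and HOXA9+MEIS1 (adjusted p = 0.0439) and lost in the others (adjusted p = 0.0515 to 0.0799). Mast cell and basophil genes, 15 measured, fell with 5 to 7 members, the same adjusted over the list alone, kept in 4 leukaemias with an estimated correlation (adjusted p = 0.0368 to 0.0439) and lost in HOXA9 (adjusted p = 0.0653). Prss34, a basophil protease gene, fell by 3.25 in MA9. Monocyte and macrophage genes, 23 measured, fell with 5 members in MA9 and 4 in PBX3+MEIS1, the same adjusted over the list alone (medians -0.76 and -0.39), calls lost with an estimated correlation (adjusted p = 0.292 and 0.589). The list did not pass in HOXA9, HOXA9+MEIS1 and HOXA9+PBX3 (medians 0.15, -0.23 and 0.03), where 3, 5 and 3 members fell and 1 rose in HOXA9.

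Interferon-stimulated genes, 21 measured, fell with 13 members in MA9, 12 in HOXA9+MEIS1, 12 in HOXA9+PBX3, 13 in PBX3+MEIS1 and 5 in HOXA9, the same counts adjusted over the list alone. The medians were -1.36, -1.49, -1.37, -1.57 and -0.24 in this order, and all 5 calls were lost with an estimated correlation (adjusted p = 0.12, 0.0939, 0.101, 0.0898 and 0.753). Oasl2, an antiviral gene, fell by 3.41 in MA9. Immediate early and heat shock genes, 18 measured, which respond to cell handling among other stimuli, fell with 10 members in MA9, 7 in HOXA9, 14 in HOXA9+PBX3 and 7 in PBX3+MEIS1, and with 11, 7, 14 and 8 adjusted over the list alone. These calls were lost with an estimated correlation (adjusted p = 0.343, 0.411, 0.168 and 0.343). In HOXA9+MEIS1, 0 members fell, over all genes and adjusted over the list alone, and the list did not pass (median -0.23, adjusted p = 0.0901). Without NC array 1, on which the list's median was 9.93 against 11.14 to 11.36 on the other NC arrays, 11 members fell in PBX3+MEIS1 and 2 in HOXA9+MEIS1 (median -0.41). Genes of MYC and ribosome biogenesis, 23 measured, rose as a list in all 5 leukaemias with medians of 0.45 to 0.56, lost with an estimated correlation (adjusted p = 0.512 to 0.656). At most 1 member passed the gene test, over all genes and adjusted over the list alone: Wdr12 in MA9 (1.09 ± 0.19) and Myc in HOXA9+MEIS1 (1.17 ± 0.21).

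**Figure D3:**
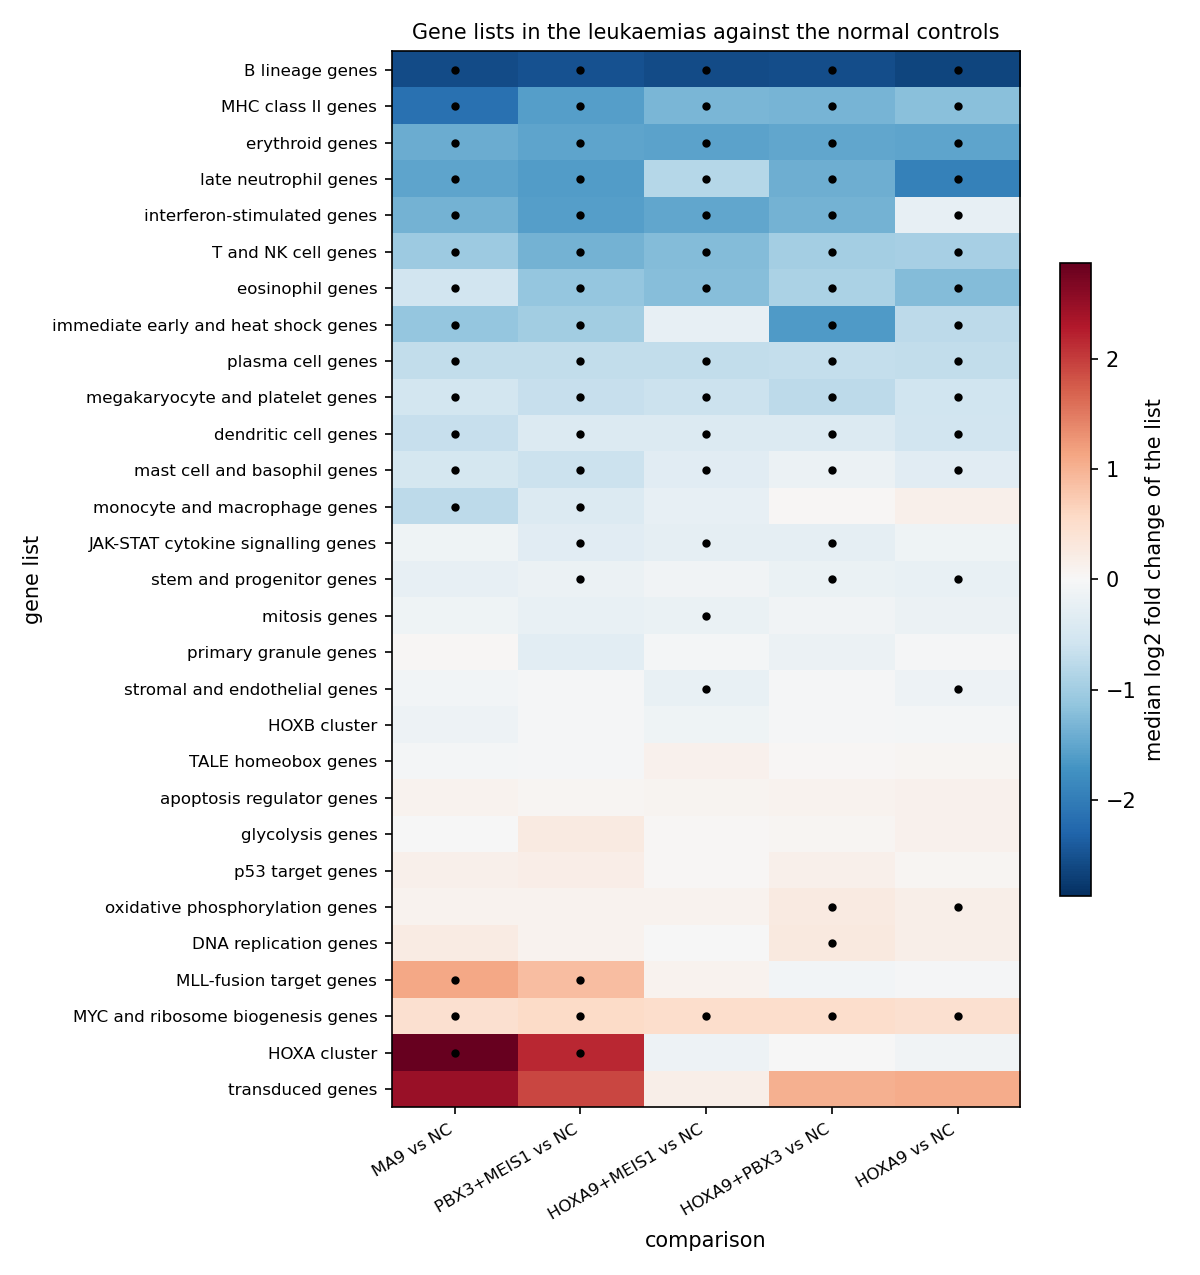
Median log2 fold change of each of 29 gene lists (vertical axis) in the 5 comparisons with NC (horizontal axis), as colour, with a dot where the camera test passed at the preset correlation. B lineage genes had medians of -2.51 to -2.63 in all 5, and the HOXA cluster had medians of 2.87 in MA9 and 2.16 in PBX3+MEIS1.

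The title of the series asks how far PBX3+MEIS1 resembles MLL-rearranged leukaemia, which was addressed by setting each leukaemia's changes beside those of MA9. Across genes, the fold changes against NC correlated with those of MA9 at 0.803 for PBX3+MEIS1, 0.776 for HOXA9+MEIS1, 0.751 for HOXA9+PBX3 and 0.718 for HOXA9. Because NC is shared, simulated data without group effects, where the fold changes hold noise alone, gave 0.377. The covariance was 0.00807 in these data and 0.211 for PBX3+MEIS1 with MA9. With single arrays left out, that of PBX3+MEIS1 ran from 0.733 (without its array 1), which is below 0.776 and 0.751, to 0.820. With the NC arrays split between both sides, the mean correlations were 0.768, 0.736, 0.716 and 0.684 in the same order. By Spearman's coefficient the order differed, with 0.627 for PBX3+MEIS1, the lowest, 0.690 for HOXA9+MEIS1, 0.660 for HOXA9+PBX3 and 0.657 for HOXA9. Without PBX3+MEIS1 array 3, a setting chosen after seeing the data, it was 0.728 for PBX3+MEIS1. Expression values of single arrays, which do not involve NC, also gave another order. Their mean correlation with MA9 arrays was lowest for PBX3+MEIS1, at 0.976 (pairs of arrays 0.962 to 0.985). It was 0.980 for HOXA9+MEIS1, 0.980 for HOXA9+PBX3 and 0.977 for HOXA9.

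Genes higher in MA9 were also higher in PBX3+MEIS1 in 140 cases (36.9% of the 379), in HOXA9+PBX3 in 102 (26.9%), and in HOXA9+MEIS1 and HOXA9 in 94 each (24.8%). Without PBX3+MEIS1 array 3, a setting chosen after seeing the data, the share for PBX3+MEIS1 was 48.8% (186 of 381). Genes lower in MA9 were also lower in 584, 520, 493 and 520 cases for PBX3+MEIS1, HOXA9+PBX3, HOXA9+MEIS1 and HOXA9. In the order of these last counts, independent calls would give 4.65, 4.37, 3.33 and 4.73 shared higher genes and 26.9, 26.3, 21.9 and 26.6 shared lower ones. The split controls gave 104.1, 85.3, 80.1 and 81.6 shared higher genes on average, a narrower gap, and 497.4, 466.1, 390.1 and 457.9 shared lower ones. These counts came from separate fits of only both compared groups, each with a part of the NC arrays. The narrower gap can therefore come from the fit as well as from the split of the controls. A total of 22 genes were higher than NC in both MA9 and PBX3+MEIS1, lower in each of the 3 HOXA9 groups than in MA9, and higher in PBX3+MEIS1 than in HOXA9+MEIS1 and HOXA9+PBX3, while PBX3+MEIS1 was not compared with HOXA9 alone. They included Hoxa5, Hoxa6, Hoxa9, Hoxa7, Hoxa3, Hoxa10, Hoxa2 and Hoxa4 as well as Eya1, which rose by 2.93 in MA9 and by 2.89 in PBX3+MEIS1. The 4 genes with the opposite directions throughout, named after their values were seen, were Alcam, a cell adhesion gene (-2.46 and -1.97), Klrb1f, BC064078 and Sntb1 (-1.32 and -1.63).

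The direct comparison of PBX3+MEIS1 with MA9 asks where both differ. There, 90 genes were higher and 155 lower in PBX3+MEIS1. Fnbp1l (2.70 ± 0.41, adjusted p = 0.000823), Col19a1 (2.64 ± 0.28), the maltase-glucoamylase gene Mgam (2.50 ± 0.49), Cnn3, which encodes an actin-binding protein (2.47 ± 0.40), Pi15 (2.43 ± 0.48) and Zg16 (2.35 ± 0.48) were higher. Tcf24 (-4.99 ± 0.20, adjusted p = 1.75e-11), the Y-linked Uty (-4.35 ± 1.04), the antiviral gene Oas1g (-3.51 ± 0.62), the transcription factor gene Dach1 (-3.20 ± 0.47), the lectin gene Mgl2 (-2.99 ± 0.30) and Stfa2 (-2.94 ± 0.61) were lower. Hoxa9 (-0.32 ± 0.24, adjusted p = 0.438), Pbx3 (0.22 ± 0.29, adjusted p = 0.673) and Meis1 (-1.52 ± 0.47, adjusted p = 0.0733) did not pass, though Meis1 passed without PBX3+MEIS1 array 1 (-2.18) and was at -0.71 without array 3. The HOXA cluster list was lower with 0 of 9 members called over all genes and 0 adjusted over the list alone (median -0.58, adjusted p = 0.0076, and adjusted p = 0.61 with an estimated correlation), and without PBX3+MEIS1 array 3 the median was -0.05. Among dendritic cell genes, Tcf4 (1.76 ± 0.22) and the receptor gene Flt3 (1.72 ± 0.43) rose, 2 of 14 members and 3 adjusted over the list alone (adjusted p = 0.00616 for the list, and adjusted p = 0.329 with an estimated correlation). The count of 245 depended on the fit: with only both groups in it 2 genes passed and 11 of the 12 genes named for their size lost the call, Tcf24 keeping it; that of Uty was also lost without MA9 array 1 or 3 or PBX3+MEIS1 array 2, and that of Mgam with array weights. The count was 421 with array weights, 143 without MA9 array 3 and 375 without MA9 array 2, and without PBX3+MEIS1 array 3 149 genes were higher and 182 lower.

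The 3 HOXA9 groups were set against MA9 in the same way. HOXA9+MEIS1 had 152 genes higher and 211 lower, HOXA9+PBX3 242 and 266, and HOXA9 281 and 322. The HOXA cluster fell with 8 of 9 members in each, also 8 adjusted over the list alone (medians -2.78, -2.70 and -2.58), and the calls were kept with an estimated correlation (adjusted p = 0.0368, 0.0377 and 0.0377). In the same order, the log2 fold changes were -5.13, -5.49 and -5.56 for Tcf24 and -5.10, -5.17 and -5.33 for Hoxa5. Those of Hoxa6 were -4.21 in HOXA9+MEIS1 and -4.19 in HOXA9+PBX3. Klrb1f, a lectin-like receptor gene of the NK family, rose by 2.73 ± 0.25, 3.09 ± 0.25 and 3.36 ± 0.25. Tmem178 rose by 3.16 ± 0.49 in HOXA9+MEIS1 and by 3.86 ± 0.49 in HOXA9+PBX3. The class I MHC gene H2-Q5 rose in HOXA9+MEIS1 (2.73 ± 0.51), the neuropilin gene Nrp1 in HOXA9+PBX3 (3.08 ± 0.34), and the interferon-inducible Ifi214 (4.49 ± 0.35) and Tnfsf8, a ligand gene of the TNF family (3.39 ± 0.13), in HOXA9. In HOXA9, Cstdc4, a stefin-like gene, fell by 5.06.

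Against MA9, monocyte and macrophage genes, 23 measured, rose with 5 members in HOXA9+PBX3 and 6 in HOXA9, and with 6 and 6 adjusted over the list alone (adjusted p = 0.183 and 0.122 with an estimated correlation, which ends both calls). Irf8, a transcription factor gene of monocytes, rose by 1.37 ± 0.14 in both. In HOXA9, 11 of 21 interferon-stimulated genes rose, also 11 adjusted over the list alone (median 1.08, adjusted p = 2.38e-13, and adjusted p = 0.128 with an estimated correlation), such as Mx1 (2.03 ± 0.25) and Oasl2 (2.46 ± 0.35). With only both groups in the fit, the count for HOXA9+MEIS1 was 199 in place of 363.

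HOXA9+MEIS1 was compared with HOXA9 for the effect of adding MEIS1. Of the genes, 118 were higher and 87 lower. Cstdc4 (4.27 ± 0.54, adjusted p = 0.000208), Stfa3 (4.14 ± 0.83) and Stfa2 (3.67 ± 0.61), all of the stefin kind, rose most. Ifi214 (-3.79 ± 0.35), the thrombin receptor gene F2r (-3.02 ± 0.40) and Tnfsf8 (-2.76 ± 0.13) fell most. Late neutrophil genes rose with 9 of 27 members and 16 adjusted over the list alone (median 1.34, adjusted p = 1.28e-26, and adjusted p = 0.0529 with an estimated correlation). They included the gelatinase gene Mmp9 (2.71 ± 0.40), Cxcr2 (2.04 ± 0.30) and the lipocalin gene Lcn2 (1.21 ± 0.18). Interferon-stimulated genes fell with 8 of 21 members, also 8 adjusted over the list alone (median -0.89, adjusted p = 4.51e-21, and adjusted p = 0.0606 with an estimated correlation). Meis1 itself did not differ past the test (-0.61 ± 0.47, adjusted p = 0.87). The count of 205 became 122 without HOXA9 array 1, 133 without HOXA9+MEIS1 array 2 and 135 (62 higher, 73 lower) with only both groups in the fit, 75 were higher and 78 lower without HOXA9 array 3, and the 9 late neutrophil genes became 14 without PBX3+MEIS1 array 3. The calls of Stfa3 (without HOXA9 array 3 or HOXA9+MEIS1 array 2) and Stfa2 (with only both groups in the fit) were lost.

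HOXA9+PBX3 was compared with HOXA9 for the effect of adding PBX3, and 15 genes were higher and 19 lower. Rnf217 (2.54 ± 0.37), Fam135a (2.43 ± 0.39) and Stfa1 (2.41 ± 0.43, adjusted p = 0.0243) rose most, and Ifi214 (-3.72 ± 0.35), F2r (-3.07 ± 0.40) and Tnfsf8 (-2.92 ± 0.13, adjusted p = 4.64e-10) fell most. Interferon-stimulated genes fell with 4 of 21 members and 9 adjusted over the list alone (median -0.93, adjusted p = 7.19e-45), and the list kept its call with an estimated correlation (adjusted p = 0.0152). The 4 were Oasl2 (-2.20 ± 0.35), Xaf1 (-1.02 ± 0.19), Usp18 (-2.19 ± 0.42) and Irf7 (-1.44 ± 0.29), the last a transcription factor gene of the interferon response, and 2 of the list fell without NC array 1. Pbx3 did not pass (0.63 ± 0.29, adjusted p = 1). The count of 34 became 21 without HOXA9 array 1, 19 without HOXA9+PBX3 array 2, 22 without HOXA9+PBX3 array 3 and 62 with array weights, and 9 genes were higher with the replicate number as a block. The call of Stfa1 was lost without HOXA9 array 2 or 3, on leaving out any single HOXA9+PBX3 array, with the replicate number as a block and with only both groups in the fit, which also ended the call of Fam135a.

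**Figure D4:**
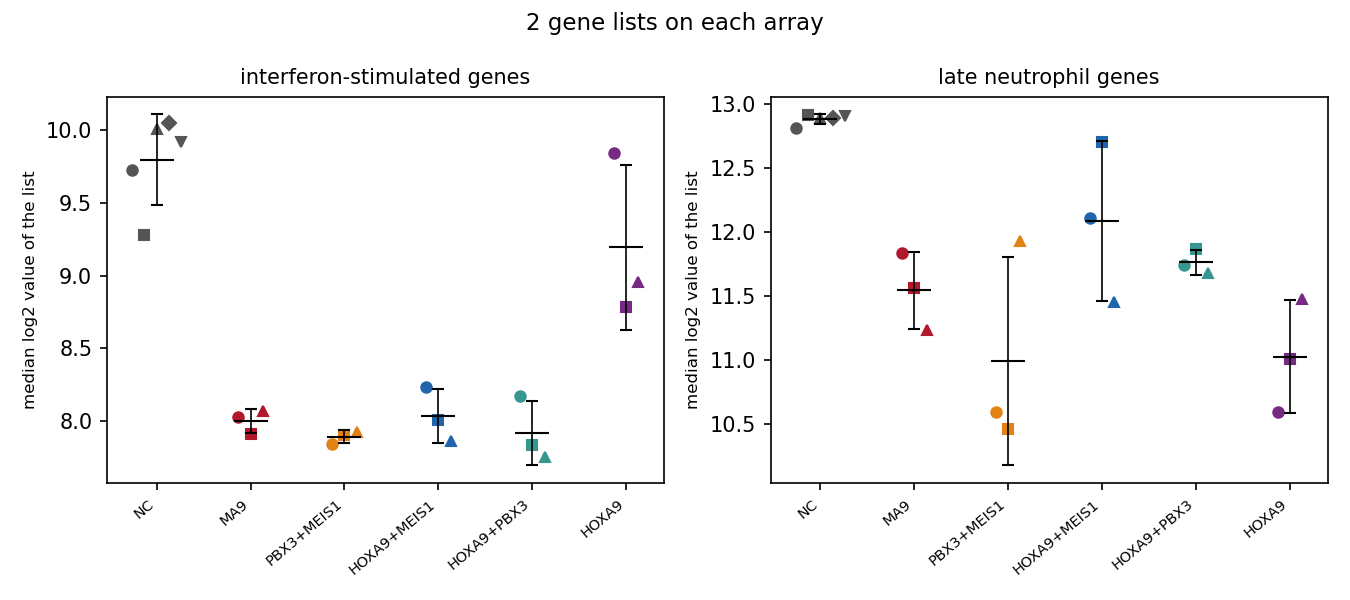
Median log2 value of the interferon-stimulated genes (left) and the late neutrophil genes (right) on each array by group, with points for arrays, a horizontal line for the group mean and bars for 1 SD. The lowest HOXA9 array had an interferon median of 8.78, above the highest of the other leukaemia arrays at 8.23.

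HOXA9+PBX3 was compared with HOXA9+MEIS1 to set both cofactors side by side, with 47 genes higher and 54 lower. The leukotriene receptor gene Cysltr1 (2.38 ± 0.50), Fam135a (2.24 ± 0.39) and Nrp1 (2.03 ± 0.34) rose most, and Plbd1 (-3.29 ± 0.50), Tfpi, which encodes an inhibitor of coagulation (-2.99 ± 0.24), and Eml5 (-2.94 ± 0.36) fell most. Pbx3 rose by 1.52 ± 0.29 (adjusted p = 0.0124), a call lost without HOXA9+PBX3 array 1 or 2. Immediate early and heat shock genes fell with 7 of 18 members and 12 adjusted over the list alone (median -1.40, adjusted p = 1.67e-23, and adjusted p = 0.0606 with an estimated correlation), among them Jund (-1.39 ± 0.24) and Btg2 (-1.55 ± 0.28). Late neutrophil genes fell with 1 of 27 members, Cxcr2 (-1.85 ± 0.30), and 5 adjusted over the list alone (adjusted p = 1.55e-15, and adjusted p = 0.131 with an estimated correlation). The count of 101 became 58, 65 and 66 without HOXA9+PBX3 array 3, 1 or 2, 59 and 166 without HOXA9+MEIS1 array 2 or 3, and 181 with array weights. With only both groups in the fit, Cysltr1, Fam135a, Nrp1 and Plbd1 lost their calls, and that of Cysltr1 was also lost without HOXA9+MEIS1 array 2 or 3, on leaving out any single HOXA9+PBX3 array and with the replicate number as a block.

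PBX3+MEIS1 was compared with HOXA9+MEIS1 and with HOXA9+PBX3, in each of which HOXA9 takes the place of 1 partner. Against HOXA9+MEIS1, 97 genes were higher and 107 lower. Fnbp1l (4.78 ± 0.41), Ikzf2, a lymphoid transcription factor gene (4.34 ± 0.42), and Xist (4.34 ± 0.81) rose most, and the Y-linked genes Uty (-5.05 ± 1.04), Kdm5d (-4.59 ± 0.98) and Sly (-3.55 ± 0.67) fell most. The HOXA cluster rose with 8 of 9 members and 8 adjusted over the list alone (median 2.35, adjusted p = 8.86e-19, and adjusted p = 0.038 with an estimated correlation, which keeps the call), and Eya1 rose by 4.04 ± 0.22. Late neutrophil genes fell with 8 of 27 members and 10 adjusted over the list alone (adjusted p = 5.07e-13, and adjusted p = 0.184 with an estimated correlation), among them Mmp9 (-2.29 ± 0.40), Cxcr2 (-1.57 ± 0.30) and the lactoferrin gene Ltf (-3.28 ± 0.70). The count of 204 was 58 with only both groups in the fit, 320 with array weights (168 higher, 152 lower) and 310 without PBX3+MEIS1 array 3 (171 higher, 139 lower), and 168 genes were lower without HOXA9+MEIS1 array 3. The calls of Uty and Kdm5d were lost with array weights, that of Kdm5d without HOXA9+MEIS1 array 1, and that of Xist with only both groups in the fit.

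Against HOXA9+PBX3, 103 genes were higher and 130 lower in PBX3+MEIS1. Xist (5.31 ± 0.81), Fnbp1l (5.25 ± 0.41) and Hoxa5 (4.31 ± 0.34) rose most, and Tmem178 (-3.43 ± 0.49), Map7d3 (-3.41 ± 0.26) and Ltf (-2.66 ± 0.70, adjusted p = 0.0415) fell most. The HOXA cluster rose with 8 of 9 members and 8 adjusted over the list alone (median 2.26, adjusted p = 8.86e-19), and the call was kept (adjusted p = 0.038 with an estimated correlation). Monocyte and macrophage genes fell with 2 of 23 members, Ccr2 (-1.39 ± 0.19) and Klf4 (-1.46 ± 0.26), and 3 adjusted over the list alone (adjusted p = 9.2e-05, and adjusted p = 0.369 with an estimated correlation). The count of 233 was 132 with only both groups in the fit, which also ended the call of Tmem178, and 359 with array weights (181 higher, 178 lower). Without PBX3+MEIS1 array 3, 177 were higher and 172 lower, and 67 were higher without HOXA9+PBX3 array 3. The call of Ltf was lost in 9 alternatives, among them those on leaving out any single HOXA9+PBX3 array and without PBX3+MEIS1 array 1 or 2.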

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

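The test of whether PBX3+MEIS1 array 3 lay nearer to another group was fixed before its result was seen, and all other tests in this part, the splits of the arrays included, were chosen after the result was seen.

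PBX3+MEIS1 array 3 stood apart from the other arrays of its group, and normal marrow cells like those of NC are argued against: a share of 22.3%, fitted on 22 late neutrophil genes, would raise the 13 B lineage genes used by a median of 1.29, but their median was -0.12 with an interquartile range of 0.656. A raised floor of low signals stays open as a part of the cause. Receptor genes that marrow cells are not known for had a median of 5.73 on array 3, against 5.19 on the highest other array. A raised floor alone is argued against as the whole cause, since it would not lower genes of high signal. Of 6862 such genes, 153 lay more than 1 below both other arrays of the group. The count was at most 81 on any other array (SD 20.8). The lower quartile of all values was 6.18 on array 3, against at most 6.09 on any other array. The upper quartile was 8.79 on array 3, against at least 8.89 on any other array. A fault that raised low and lowered high signals together stays open, since the fallen genes do not count against it. RNA quality was not tested. An array wholly of NC or of 1 of the HOXA9 groups is argued against by the mean of the HOXA cluster, which was 8.11 on array 3, at most 6.89 on the 9 arrays of the HOXA9 groups (SD 0.0625) and at most 7.01 in NC (SD 0.0799). On an array of MA9 that mean cannot decide, since the other PBX3+MEIS1 arrays (9.53 and 9.34) lay at the level of MA9 (9.36 to 9.60). Array 3 was below both groups, so an MA9 array stays open by this mean. Tcf24, a single gene, was at 7.84 on array 3 and at 12.4 or more in MA9. The test fixed beforehand did not exclude another group: 49.4% of 310 genes were nearer to the other PBX3+MEIS1 arrays than to HOXA9+MEIS1, under the limit of 50. The share was 51.6% for HOXA9+PBX3, 53.2% for MA9 and 56.6% for HOXA9. Arrays of those groups, judged by the rest of their own group, had lower shares throughout. These were 15.9%, 41.6% and 4.8% for MA9 arrays 1, 2 and 3. The ranges were 3.98% to 31.5% for HOXA9+MEIS1, 2.24% to 4.39% for HOXA9+PBX3 and 2.80% to 7.87% for HOXA9. A mixture with cells of another leukaemia was not tested and stays open, and no biological explanation was tested.

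Xist or the Y-linked genes Kdm5d, Eif2s3y and Uty varied within 4 of the 6 groups. Both varied in MA9, only the Y-linked genes in NC and HOXA9+PBX3, and only Xist in HOXA9+MEIS1. All 3 HOXA9 arrays had Xist low and the Y-linked genes high, and all 3 PBX3+MEIS1 arrays the reverse. The pattern of 1 sex was broken on 8 of 20 arrays. NC arrays 1 and 2 had Xist and all 3 Y-linked genes high, and MA9 array 2 had Xist, Kdm5d and Uty high, which argues against cells of 1 sex there. The HOXA9+MEIS1 arrays had Kdm5d and Uty high and Eif2s3y low (Xist on array 1 was 10.15, just over the limit of 9.96 between high and low). HOXA9+PBX3 array 2 had all 4 low. On MA9 array 3, Xist (9.90) and Kdm5d (7.26, limit 7.39) lay just under their limits. For the HOXA9+MEIS1 arrays, HOXA9+PBX3 array 2 and MA9 array 3 the test cannot decide, since lost Y-linked signal or a value beside the limit breaks the pattern too. Sex-linked genes carrying the counts of changed genes is argued against, since leaving out genes on X and Y lowered a count by at most 6.86% (204 to 190 for PBX3+MEIS1 against HOXA9+MEIS1). An effect of sex on genes of other chromosomes was not tested. It cannot be told apart from that of the group for HOXA9 and PBX3+MEIS1, where the pattern goes with the group. The same limit holds for HOXA9+MEIS1, whose Y-linked genes had the same pattern on all 3 arrays. Mixed donors, loss of the Y chromosome in leukaemic cells and mixed-up samples stay open, as none was tested.

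Interferon-stimulated genes were higher with HOXA9 alone than in the 4 other leukaemias, by a median of 0.899 on the log2 scale, and a single unusual array is argued against, since the lowest HOXA9 array had a list median of 8.78 and the highest of the 12 others 8.23. More lymphoid cells are argued against by a median of -0.0664 for B lineage genes and 0.0652 for T and NK cell genes. More monocytes and macrophages are argued against, for HOXA9 minus HOXA9+PBX3, by a median of 6.67e-05 (SE 0.0515) beside 0.934 for the interferon list. Monocyte and macrophage genes were higher in HOXA9 than in MA9, HOXA9+MEIS1 and PBX3+MEIS1 by medians of 0.513, 0.303 and 0.461, but also in HOXA9+PBX3, by 0.526, 0.335 and 0.384, where the interferon medians were only 0.0552, 0.0228 and 0.155, which argues against their number as the cause there too. A difference made by the transduced genes was not tested and stays open, as does one in infection, housing or processing between groups.

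Among the 5 NC arrays, 1 array lay far from the other 4 for several genes named here, where chance does so for about 1 in 20 groups. This held for 12 of 97 genes examined, against 4.85 by chance. NC array 1 was apart for Hoxa9 at a log2 value of 7.50 (others 6.94 to 7.05), Ptgs2 at 8.43 (others 11.5 to 11.8), Ccr2 at 11.88 (others 11.3 to 11.4) and the heat shock gene Hspa1a at 7.11 (others 11.6 to 12.6), the last a gene picked after its values were seen. NC array 2 was apart for Gpnmb at 7.41 (others 7.82 to 7.95), Colec12 at 7.08 (others 7.57 to 7.72), Ifi214 at 5.86 (others 6.97 to 7.37), Cd3g at 9.32 (others 10.2 to 10.5), Cd79a at 10.38 (others 10.8 to 10.9) and Eya1 at 8.31 (others 8.69 to 8.78). NC array 4 was apart for Slc18a1 at 6.25 (others 6.46 to 6.52) and Lcn2 at 13.16 (others 13.07 to 13.08).

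Probe sets without a single gene symbol, 17824 in number, were not part of the comparisons. Of these, 26 were higher and 232 lower in all 5 leukaemias than in NC, a signal in data that the comparisons did not use.

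The arrays were also split in every other way into groups of the same sizes. For each comparison with NC, 1 of 56 splits, the real one, gave as many changed genes, the smallest share this test can give. Chance alone is argued against by this share, which is under 0.05, but it is not excluded. Every other split mixed NC and leukaemia arrays, so any difference between the groups, whatever its cause, favours the real one. These tests also share the NC arrays and are not independent. The highest other split gave 21 genes for MA9 (real count 1148), 9 for HOXA9 (1043) and 9 for HOXA9+MEIS1 (828). It gave 12 for HOXA9+PBX3 (1014) and 97 for PBX3+MEIS1 (1047). For the others, 10 splits are too few for a share under 0.05. The real counts and the highest other counts were 245 and 103 for PBX3+MEIS1 against MA9, 363 and 69 for HOXA9+MEIS1 against MA9, 508 and 1 for HOXA9+PBX3 against MA9, and 603 and 3 for HOXA9 against MA9. They were 205 and 1 for HOXA9+MEIS1 against HOXA9, 34 and 1 for HOXA9+PBX3 against HOXA9, 101 and 0 for HOXA9+PBX3 against HOXA9+MEIS1, 204 and 106 for PBX3+MEIS1 against HOXA9+MEIS1, and 233 and 1 for PBX3+MEIS1 against HOXA9+PBX3.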

How the results depend on the processing

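The fits without X and Y genes, the list tests without NC array 1 or PBX3+MEIS1 array 3 and the Spearman correlation and shared calls without the latter array were chosen after the data were seen. Of 4005 values of 228 pairs of a named gene and a comparison under the alternatives, 3899 kept their direction and side of the threshold, 80 lost the call, 26 gained it and 0 reversed. The setting with the highest number of losses, 22 of the 80, was only both groups in the fit, which has fewer arrays for the variance. Fewer arrays are not the whole cause. With equally many arrays, the count went from 508 to 440 for HOXA9+PBX3 against MA9, but from 245 to 2 for PBX3+MEIS1 against MA9. The main fit takes 1 spread per gene for all groups, though array pairs correlated at 0.968 to 0.991 within PBX3+MEIS1 and 0.995 to 0.996 within HOXA9+PBX3. Its standard errors can therefore be too small for groups of wide spread. Without a fold minimum, which admits smaller changes, the counts were 5764 for MA9, 5007 for HOXA9, 4069 for HOXA9+MEIS1, 5198 for HOXA9+PBX3 and 5131 for PBX3+MEIS1 against NC, with more genes higher than lower in MA9, HOXA9 and HOXA9+PBX3. Against MA9 they were 1009 for PBX3+MEIS1, 1031 for HOXA9+MEIS1, 1508 for HOXA9+PBX3 and 1684 for HOXA9. They were 412 for HOXA9+MEIS1 against HOXA9, 204 for HOXA9+PBX3 against HOXA9+MEIS1, and 583 and 788 for PBX3+MEIS1 against HOXA9+MEIS1 and HOXA9+PBX3. With only both groups in the fit the counts were 2 for PBX3+MEIS1 against MA9, 199 for HOXA9+MEIS1 against MA9, 135 for HOXA9+MEIS1 against HOXA9, and 58 and 132 for PBX3+MEIS1 against HOXA9+MEIS1 and HOXA9+PBX3. With array weights, of which PBX3+MEIS1 array 3 had the lowest (0.116), they were 421 for PBX3+MEIS1 against MA9, 62 for HOXA9+PBX3 against HOXA9, 181 for HOXA9+PBX3 against HOXA9+MEIS1, and 320 and 359 for PBX3+MEIS1 against HOXA9+MEIS1 and HOXA9+PBX3; the cause was not tested. Leaving out each array in turn gave 143 to 375 genes for PBX3+MEIS1 against MA9 (without MA9 array 3 and MA9 array 2), 122 to 242 for HOXA9+MEIS1 against HOXA9, 19 to 31 for HOXA9+PBX3 against HOXA9, 58 to 166 for HOXA9+PBX3 against HOXA9+MEIS1 and 145 to 310 for PBX3+MEIS1 against HOXA9+MEIS1; the cause was not tested. The correlation with MA9 ran from 0.733 (without its array 1) to 0.820 (without its array 3) for PBX3+MEIS1 and from 0.719 (without MA9 array 2) to 0.763 for HOXA9+PBX3. With NC split between both sides it was 0.716, and that of HOXA9 was 0.684. By Spearman's coefficient the correlations were 0.627, 0.690, 0.660 and 0.657 for PBX3+MEIS1, HOXA9+MEIS1, HOXA9+PBX3 and HOXA9, and 0.728 for PBX3+MEIS1 without array 3. Of the 156 list tests past the threshold, 27 held with an estimated correlation, which was above the preset 0.01 in all 406 tests. By fry 113 passed.

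Replicate numbers did not pair the arrays: 45 pairs of equal number had a median correlation of 0.0021 after removing group means, against -0.00302 for 120 pairs of unequal number. With the replicate block, 1088 genes changed for MA9 against NC and 194 for PBX3+MEIS1 against MA9, and 160 list tests passed. Signal over background cannot be read from these values, so that changes near the level of receptor genes are the least certain.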

Other observations

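The family of stefins and stefin-like genes, inhibitors of cysteine proteases found in myeloid cells, was chosen after its values were seen and no tests were planned for it. Of 13 measured members, 8 were higher in MA9 than in NC (median log2 fold change 1.28) and 8 in HOXA9+MEIS1 (median 1.18), whereas in HOXA9 0 were higher and 2 lower (median -0.29). In HOXA9+PBX3 and PBX3+MEIS1, 2 each were higher than in NC (medians 0.03 and 0.21). HOXA9 against MA9 had 8 members lower (median -2.19), and HOXA9+MEIS1 against HOXA9 had 7 higher (median 2.61). HOXA9+PBX3 had 2 higher than HOXA9 (median 1.18) and 3 lower than MA9 (median -0.95). In PBX3+MEIS1, 4 were lower than in MA9 (median -1.16). These medians kept their sign after centring or a further quantile normalization. The first choice of members by name also took in Cstad, a gene of another kind, which was then left out; with it, the 14 genes had the same counts and a median of 1.96 for HOXA9+MEIS1 against HOXA9. The genes are near copies of each other, and whether probes are shared between members was not tested.

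The lists of the HOXB cluster (10 measured), TALE homeobox genes (10) and apoptosis regulators (19) passed in 0 of the 14 comparisons by camera, the lowest adjusted p being 0.0709, 0.512 and 0.135.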
